A study of Mus musculus with 3 samples.

How the data were processed

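Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on hepatoblasts, the fetal progenitors of hepatocytes and bile duct cells. The cells came from pooled wild-type C57BL/6 mouse livers at embryonic day 14.5 and had been enriched by magnetic sorting for DLK1, a surface protein of hepatoblasts, per the labels' protocols. There were 3 libraries: 1 with an antibody against HNF4A, 1 with an antibody against FOXA2 and 1 of input chromatin without immunoprecipitation. With 1 library per group no comparison has a replicate check, and every test below describes these lists of peaks, not differences between animals or conditions.

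The authors deposited 1 list of regions per library, called separately, without a header. Each line holds a chromosome, a start, an end and a whole-number score. The deposited score has no stated definition; it was treated as the authors' own value of a peak and compared only within its list, because its scaling to library size is not given in the sources used here. The lowest score was 16 in the HNF4A list, 11 in the FOXA2 list and 12 in the input list, and 10.1%, 16.5% and 17.1% of peaks stood at those values, so each list ends at a threshold. The aligner, the peak caller and its threshold are not given in the sources used here. The genome build is mm9, per the submitters' processing notes. The depth of the libraries is unknown. Neither ChIP list holds a nuclear region that overlaps an input region, as if such regions had been left out before deposit, but no source used here states that step. How a peak of low depth would fare at each threshold is therefore not known, and a peak missing from a list is not evidence that the factor was absent there.

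Positions were taken as 1-based with both ends included, because the first mitochondrial peak starts at 1 and the shortest width is then 200 bp in every list. Chromosome names were matched across files after removing a prefix, since the mitochondrial chromosome is written differently in the HNF4A and input files. A closing line of the FOXA2 file that holds no region was skipped. Each file maps to a single sample.

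A peak was called shared when it overlapped a peak of the other factor by at least 1 bp, and single-factor otherwise. The number of shared peaks was set against 1000 random placements in which each FOXA2 peak was moved by 10 to 100 kb in either direction, which keeps it in its own neighbourhood. The p-value is from this one-sided permutation test, and the smallest that 1000 placements can give is 0.001. Overlap with input was measured in the same way by moving the input peaks. Scores of shared and single-factor peaks were compared within each list by a two-sided permutation test of the difference in median log2 score, with 100000 resamples, whose smallest p-value is 1e-05. Benjamini-Hochberg adjustment was made over the 2 lists. Intervals of that difference are bootstrap intervals over peaks, from 2000 resamples. Overlapping peaks of both factors were merged into sites, sites at most 12.5 kb apart were joined into clusters, and clusters of 5 or more sites were counted against 200 local shifts of the sites. Clusters of peaks were joined in the same way without merging. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Neighbouring peaks are not independent, so these intervals are too narrow where peaks cluster. For the trend with score, each list was divided into 10 groups of nearly equal size in order of score, with ties broken at random from a fixed seed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

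The methods were tested on simulated data for the HNF4A and FOXA2 overlap. In 40 simulated FOXA2 lists of 9338 peaks without a relation to HNF4A the placement test made 0 calls. These lists were made by the same local shifts that the test uses. The result therefore checks the computation, not how the test behaves on other unrelated lists. Where 2000 peaks were planted close to HNF4A centres, so that they had to overlap, a mean of 1983 was counted over 5 simulations. Estimated chance overlap had been subtracted from that count. The score test called 0 of 40 random splits and 40 of 40 splits with a 1.2-fold rise.

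The regions named in the text were fixed by a rule before the data were examined: the 10 highest-scoring peaks of each factor that overlap no input peak. Other positions that are named, in clusters, among the strongest shared pairs or in the input and mitochondrial lists, were chosen after their values were seen. Other settings chosen before the data were examined concerned the definition of a shared peak, the score threshold, input overlap and the random placement; further ones were added after seeing the data. The distance to transcription start sites, the 13 motif consensus sequences and the 15 gene lists that were also planned, which cover hepatocyte, hepatoblast, cholangiocyte, Hippo pathway, blood, endothelial, stellate, other endoderm and neuronal genes, were not analysed here, since no genome sequence or annotation of the mm9 build was used. Peaks are therefore given by position, without gene names and without a statement on exons, introns or promoters.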

Results

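HNF4A and FOXA2 occupancy was mapped in DLK1-sorted hepatoblasts of the embryonic day 14.5 mouse liver. HNF4A is a nuclear receptor that drives hepatocyte gene expression, and FOXA2 is a forkhead factor that can bind closed chromatin and whose loss together with FOXA1 prevents liver specification. The HNF4A library gave 11703 peaks, the FOXA2 library 9338 peaks and the input library 1263 peaks. HNF4A peaks covered 5.46 Mb and had a median width of 430 bp (interquartile range 366 to 530 bp). FOXA2 peaks covered 3.84 Mb with a median width of 367 bp (331 to 425 bp). Input regions covered 1.11 Mb and were broader, with a median of 613 bp. In the input list 25.5% of regions exceeded 1 kb, against 0.769% of HNF4A peaks and 1.68% of FOXA2 peaks. There were no replicate libraries for any of these values.

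The first comparison asked how far the sites of both factors coincide. HNF4A and FOXA2 occupied a common set of elements: 2871 FOXA2 peaks, 30.7% of that list (95% Wilson interval 29.8 to 31.7%), overlapped 2858 HNF4A peaks, 24.4% of the HNF4A list (23.7 to 25.2%). The remaining 8845 HNF4A peaks and 6467 FOXA2 peaks were single-factor peaks. FOXA2 peaks moved by 10 to 100 kb within their neighbourhoods overlapped HNF4A at a median of 89 peaks, or 0.953% of the list, and at most 119. The observed number was thus 32.3-fold above the median placement (one-sided permutation test by random placement, p = 0.001, the smallest that 1000 placements can give). The size of this fold depended on the placement, at 75.6-fold when FOXA2 peaks were placed anywhere on their chromosome and 19.5-fold when they were moved by only 2 to 10 kb. Placed peaks can fall in any sequence, whether or not a peak could be called there. The fold therefore does not separate joint occupancy from open chromatin common to both factors. Both lists lack nuclear regions that overlap the same input list, and both depend on thresholds of unknown depth, so these shares do not give the fraction of sites bound by a single factor.

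Shared peaks were also centred on the same position. The centres of the 2879 overlapping pairs lay a median of 59 bp apart (interquartile range 27 to 106 bp), and 72.7% of pairs had centres within 100 bp. Pairs that overlapped after random placement had centres a median of 213 bp apart, and 23.1% of them lay within 100 bp. Over the whole FOXA2 list, 2075 peaks had an HNF4A centre less than 100 bp away, against a median of 21 placed peaks. A further 603 peaks lay at 100 to 200 bp, also against 21. The excess shrank with distance, to 1.77-fold at 500 to 1000 bp and 1.34-fold at 1000 to 2000 bp. Farther out, observed numbers were below placed ones, at 0.94 times at 2000 to 5000 bp and 0.76 times at 5000 to 10000 bp. They were 0.58 times at 10000 to 20000 bp and 0.50 times from there to 100000 bp. Each peak is counted once, at its nearest HNF4A centre. The placement moved each shared peak 10 to 100 kb from its own HNF4A partner, which adds placed peaks up to that distance. The lower numbers therefore do not show that FOXA2 peaks avoid HNF4A at these distances. Beyond 100 kb from any HNF4A centre lay 2131 FOXA2 peaks, 22.8% of the list, against a median of 2204 placed peaks. Moves of at most 100 kb limit how far this last count can change.

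**Figure D1:**
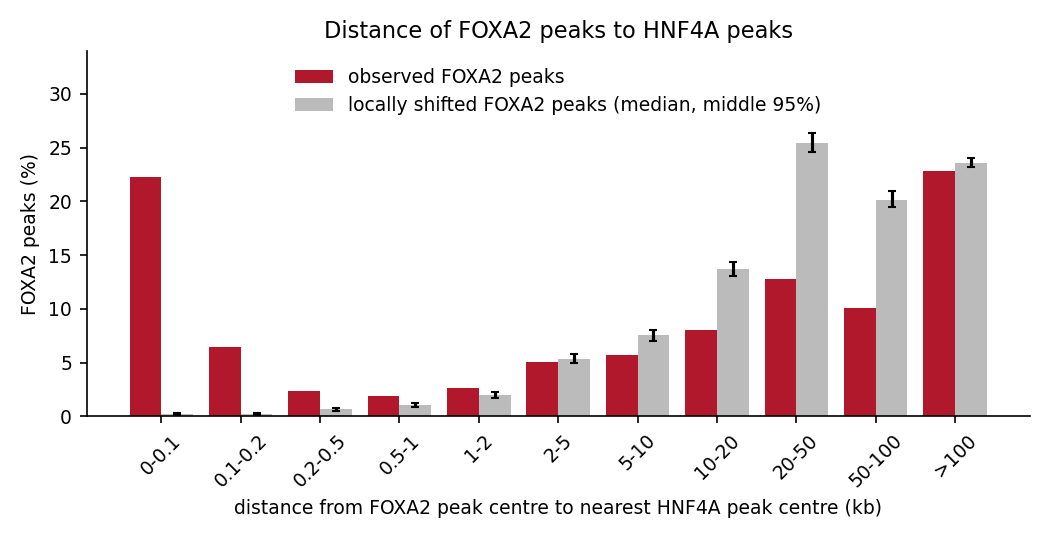
Share of FOXA2 peaks (y axis, percent of 9338 peaks) by distance from the peak centre to the nearest HNF4A peak centre (x axis, kb). Red bars are the observed peaks and grey bars the median of 1000 local shifts, with black bars for their middle 95%; the observed peaks exceed the shifts most at under 0.1 kb, with 22.2% of the list.

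The next comparison related sharing to the authors' score within each list. Shared sites were the higher-scoring ones for both factors. Shared HNF4A peaks had a median score of 27 (interquartile range 20 to 40) against 22 (18 to 31) for HNF4A-only peaks. This is a difference of 0.30 on the log2 scale (bootstrap interval 0.24 to 0.35; two-sided permutation test, adjusted p = 1e-05, the smallest possible). Shared FOXA2 peaks had a median of 19 (14 to 30) against 14 (12 to 19) for FOXA2-only peaks, a difference of 0.44 (0.44 to 0.51; permutation test, adjusted p = 1e-05). Medians of whole-number scores take few values, so the lower bound for FOXA2 equals its estimate. That interval is therefore coarse. The distributions overlapped widely. With tied pairs split evenly, a shared peak ranked above a single-factor peak in 61.8% of random pairs in the HNF4A list (60.5 to 63.0%). In the FOXA2 list this was 66.9% (65.7 to 68.1%). Whole-number scores tie often, so the part of pairs with a strictly higher shared score is lower.

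Sharing increased with score in both lists once the lowest groups were passed. In the lowest of 10 score groups, 16.5% of HNF4A peaks (14.5 to 18.7%) were shared with FOXA2, and in the highest 40.2% (37.4 to 43.1%). For FOXA2 the share was 19.6% (17.2 to 22.3%) in the lowest group, 17.6% (15.3 to 20.1%) in the third and 59.9% (56.7 to 62.9%) in the highest. Overlap after local shifts stayed between 0.682% and 0.851% over the HNF4A groups and between 0.838% and 1.07% over the FOXA2 groups. Across the 2879 shared pairs the scores of both factors were only weakly correlated, with a Spearman rho of 0.13 (bootstrap interval 0.10 to 0.17) and a Pearson r of 0.14 on log2 scores. The permutation p for rho was 0.0001, the smallest that 10000 permutations can give. This correlation is across peaks, which are not independent replicates.

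**Figure D2:**
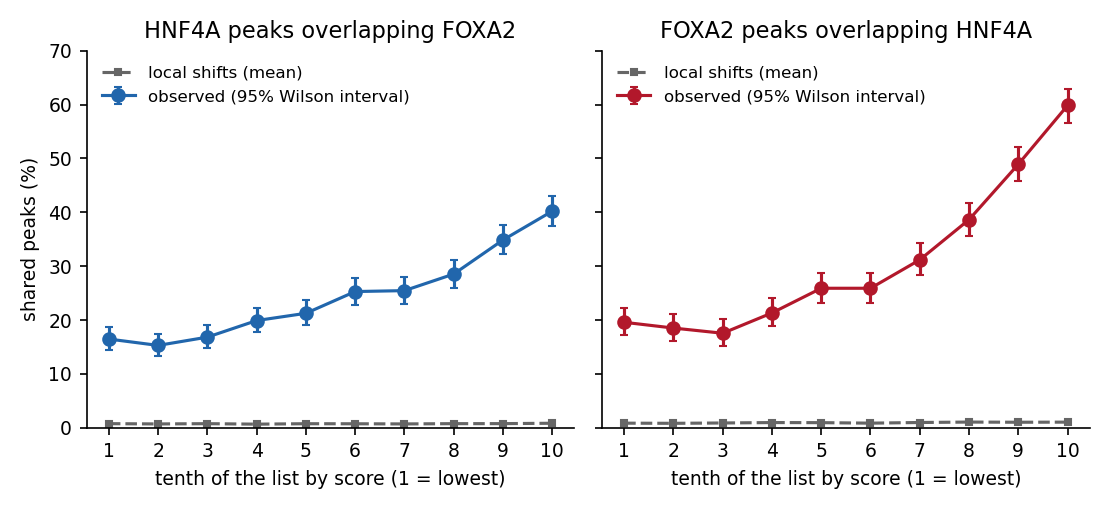
Percent of peaks shared with the other factor (y axis) in 10 groups of increasing score (x axis), for HNF4A peaks on the left and FOXA2 peaks on the right. Points are observed shares with 95% Wilson intervals and grey squares the mean of 200 local shifts; the share reaches 40.2% in the highest HNF4A group and 59.9% in the highest FOXA2 group.

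Of the 10 highest FOXA2 peaks, with scores of 106 to 165, 9 overlapped an HNF4A peak. The highest lay on chromosome 1 at 66947560 to 66947912 (mm9, score 165) and met an HNF4A peak of score 43 whose centre was 21 bp away. The second, on chromosome 9 at 42083138 to 42083476 (score 149), met an HNF4A peak of score 75. The third, on chromosome 9 at 53164621 to 53165013 (score 143), met one of score 23. The exception was chromosome 1 at 80424491 to 80424849 (score 114), whose nearest HNF4A centre was 577566 bp away. The other six lay on chromosomes 3, 4, 11 and 13, with HNF4A scores of 20 to 55 and centres 8 to 79 bp apart.

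Of the 10 highest nuclear HNF4A peaks, with scores of 119 to 161, 4 overlapped a FOXA2 peak. The highest, on chromosome 3 at 108517756 to 108518119 (score 161), had no FOXA2 overlap, and its nearest FOXA2 centre lay 2062 bp away. The second, on chromosome 8 at 3256539 to 3256896 (score 149), overlapped a FOXA2 peak at the lowest score of that list, 11. The third, on chromosome 7 at 20270693 to 20271061 (score 142), was shared with a FOXA2 peak of score 28. Chromosome 5 at 65748053 to 65748502 (score 139) was shared with a FOXA2 peak of score 12. Chromosome 19 at 38265932 to 38266336 (score 120) was shared with one of score 47. The other unshared ones were chromosome 7 at 31260016 to 31260411 (score 140), 116769 bp from any FOXA2 centre, and chromosome 3 at 157656367 to 157656734 (score 133), 63989 bp away, together with 3 regions closer to FOXA2. These were chromosome 5 at 65197486 to 65197891 (score 138), 5554 bp away, chromosome 15 at 77753177 to 77753593 (score 128), 10672 bp away, and chromosome 11 at 55021915 to 55022247 (score 119), 1584 bp away. The numbers of shared peaks, 9 and 4 of 10, did not differ at the 0.05 threshold (two-sided Fisher's exact test, p = 0.0573).

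Shared pairs were also ranked by the lower of their percentiles in the HNF4A and FOXA2 lists, so that both scores had to be high. By that rule the first was on chromosome 10, with an HNF4A peak at 120923317 to 120923768 (score 89) and a FOXA2 peak at 120923437 to 120923784 (score 80). The next was on chromosome 6, with HNF4A at 116585455 to 116585924 (score 90) and FOXA2 at 116585424 to 116585892 (score 72). The third was on chromosome 11, with HNF4A at 79585020 to 79585448 (score 110) and FOXA2 at 79584912 to 79585254 (score 70).

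Peaks of both factors also lay in dense clusters, a pattern examined after the data were seen. To count a shared region once, overlapping peaks were merged into 18162 sites, and sites at most 12.5 kb apart were joined. Clusters of 5 or more sites numbered 222, against a median of 87 and at most 111 over 200 local shifts. Of these, 175 held both factors, or 78.8%, which lay within the range of the shifts (median 73.5%, at most 81.5%). Without peaks within 10 kb of an input region there were 187 such clusters, against a median of 63. Counted by peaks, where a shared site counts for each factor, 436 clusters held 5 or more, and 399 did without peaks beside input. Of the latter, the one with the most peaks lay on chromosome 5 at 90843248 to 90923884. It held 14 HNF4A peaks with scores of 16 to 80 and 12 FOXA2 peaks with scores of 11 to 50 over 80.6 kb, and 8 of each were shared. Next came chromosome 18 at 85018120 to 85091522, with 12 HNF4A and 4 FOXA2 peaks. Chromosome 11 at 83691269 to 83750299, with 6 HNF4A and 7 FOXA2 peaks, and chromosome 7 at 20261979 to 20286633, with 11 HNF4A and 2 FOXA2 peaks, followed with 13 peaks each.

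**Figure D3:**
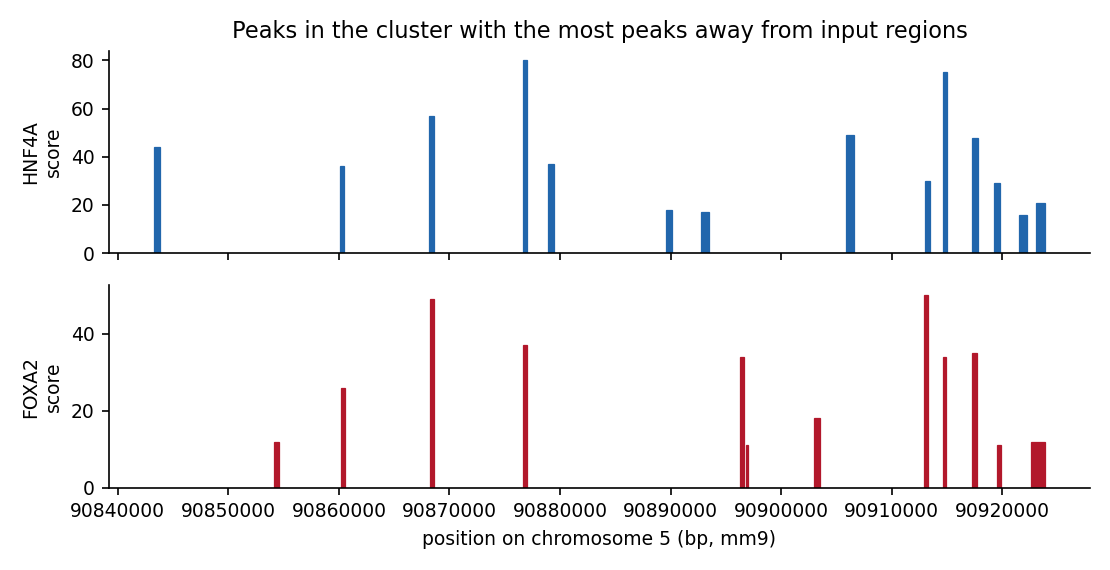
Scores of HNF4A peaks (upper panel) and FOXA2 peaks (lower panel, own y scale) along chromosome 5 (x axis, mm9 position in bp) in the cluster that held the most peaks away from input regions. Each bar spans 1 peak; 8 of 14 HNF4A peaks overlap a FOXA2 peak, and 8 of 12 FOXA2 peaks overlap an HNF4A peak.

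Sharing varied between autosomes. The shared part of the FOXA2 list ranged from 23.3% on chromosome 17 (19.3 to 28.0%) to 38.6% on chromosome 6 (34.6 to 42.8%). The shared part of the HNF4A list ranged from 18.3% on chromosome 17 (15.0 to 22.1%) to 29.9% on chromosome 12 (25.9 to 34.1%). The spread over the 19 autosomes exceeded that of randomly reassigned peaks in both lists (permutation test of a chi-square statistic with 100000 resamples, adjusted p = 4e-05 for FOXA2 and 0.00013 for HNF4A). Clustering of neighbouring peaks was not kept in that reassignment. On the X chromosome 42 of 215 FOXA2 peaks were shared, 19.5% (14.8 to 25.3%), against 40 of 132 HNF4A peaks, 30.3% (23.1 to 38.6%). Shared regions are nearly the same in both lists, so these shares differ through the unshared X peaks, 173 for FOXA2 and 92 for HNF4A. Without peaks within 10 kb of an input region the unshared X peaks numbered 107 and 86, and the shared parts on X were 24.6% for FOXA2 and 28.9% for HNF4A.

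The last comparison was with input chromatin, which shows where regions are called without an antibody. Nuclear regions that overlap input may have been left out before deposit, in which case the overlaps of 0 below were fixed by that step. They do not show that the ChIP lists are free of background. No FOXA2 peak overlapped an input region, 0 of 9338. Nuclear input regions moved locally met a median of 78 FOXA2 peaks and at least 56 (one-sided permutation test, p = 0.001). In the HNF4A list 2 of 11703 peaks overlapped input, and both were mitochondrial; none of the 11700 nuclear peaks did, against a median of 5 and a range of 0 to 15 after local shifts (one-sided permutation test, p = 0.00699). Input regions were unevenly spread, with 18.2% on X, 12.1% on chromosome 4, 11.8% on chromosome 1, 11% on chromosome 5, 8.95% on chromosome 8 and 8.47% on Y. The 3 highest input regions lay on chromosome 2 between 98502280 and 98507485 (scores of 338, 236 and 233), and the next on chromosome 9 at 2999923 to 3001062 (score 227).

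FOXA2 peaks gathered beside input regions. Within 10 kb of an input region lay 510 FOXA2 peaks, 5.46% of the list (5.02 to 5.94%). Input regions moved by 200 to 1000 kb had a median of 177 and at most 229 FOXA2 peaks that close (one-sided permutation test by random placement, p = 0.001). The same count for HNF4A was 57 peaks, 0.487% of the list (0.376 to 0.630%), against a median of 67 and at most 99. Each input region was moved on its own, which breaks up groups of neighbouring regions, so the spread of placements is likely too narrow. FOXA2 peaks beside input were partly concentrated: clusters of 5 or more peaks with FOXA2 alone numbered 35, and 6 without peaks beside input. Those with HNF4A alone numbered 12 in both cases. The FOXA2 peaks beside input had a median score of 13, against 15 for the others, and 4.31% of them were shared with HNF4A, against 32.3% of the others. Of the 57 HNF4A peaks beside input, 33.3% were shared with FOXA2, against 24.4% of the other HNF4A peaks. No interval was computed for this share of few peaks. Shared regions beside input are nearly the same in both lists. The shares of 4.31% and 33.3% therefore differ mainly through the unshared peaks, which are more numerous for FOXA2.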

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

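The contrasts between the lists, the test of low-scoring peaks on the sex chromosomes and the test on the mitochondrial peaks were chosen after the data were seen; the tests of width, of score correlation and of peaks beside input regions were written down before their results. The design names no group beyond antibody and input, so no biological explanation was tested for these patterns apart from a property common to both libraries, such as open chromatin, in the test of score correlation.

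The score contrast between shared and single-factor peaks was larger for FOXA2 than for HNF4A. With tied pairs split evenly, a shared peak ranked above a single-factor peak in 66.9% of pairs in the FOXA2 list and in 61.8% in the HNF4A list. The difference was 5.14 percentage points (interval 3.49 to 6.80 from separate bootstraps of the lists). Those bootstraps take the lists as independent although their shared regions are common. The lists also end at different thresholds. The FOXA2 list holds 510 peaks beside input, with a median score of 13 and 4.31% shared, against 57 such HNF4A peaks. The contrast was not repeated without these peaks or at a like threshold, so it may not be a difference between the factors. The rise of sharing with score could come from wider peaks meeting others by chance, but median width was 402 bp in the highest and 444 bp in the lowest HNF4A score group, and 353 and 374 bp for FOXA2. The chance overlap of the highest minus the lowest score group came to at most 0.00475 of the observed difference. Chance overlap was at most 1.07% in any group, so this ratio could hardly have been large. The narrower peaks of the highest groups are what argues against width. A single property of both libraries that sets both scores, such as open chromatin, would need scores that rise together. The rho of 0.13 across shared pairs (interval 0.10 to 0.17) lay under the 0.3 named in advance for that explanation. It was not under the 0.1 named against it, so this remains open. Only pairs in which both peaks passed their thresholds entered rho, and scores tie often, which can lower it. A low rho therefore could not have counted against this explanation.

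FOXA2 peaks were more often on X and Y, with 243 of 9338 peaks (2.60%) against 142 of 11703 HNF4A peaks (1.21%), a ratio of 2.14 (95% interval 1.75 to 2.63). Peaks beside input regions may account for part of this: without peaks within 10 kb of an input region the ratio was 1.59 (1.25 to 2.02). A deeper reach of the FOXA2 list into low scores is also possible, since among peaks at or above each list's median score the ratio was 1.5 (1.07 to 2.11). Without peaks beside input the whole interval lay above the bound named in favour of that explanation. The ratio of 1.59 exceeded the 1.5 named against it, but its interval reached below 1.5. A surplus was thus left in these lists after removal of peaks within 10 kb of input. The interval counts peaks as independent, so it is too narrow where they cluster. Background farther than 10 kb from a called input region would also stay in, so the part of background is not settled. For low scores the interval crossed both bounds, because the peaks on X and Y are few, so that explanation remains open. The odds ratio of sharing on X against autosomes, FOXA2 over HNF4A, was 0.399 (0.24 to 0.66) over all peaks and 0.539 (0.31 to 0.94) without peaks beside input, but this decides nothing further, since the shared regions are nearly the same in both lists and the ratio restates the surplus of unshared FOXA2 peaks on X.

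The highest scores of the HNF4A list, 294 and 280, belonged to mitochondrial peaks at 1 to 6479 and 10930 to 15810. The FOXA2 list holds 0 mitochondrial peaks and the input list 8. Of the 3 mitochondrial HNF4A peaks 2 overlapped input regions, and 0 nuclear HNF4A peaks did. A possible explanation is that the chromosome is written differently in the HNF4A and input files, so overlaps with input were not removed there. It was drawn from these counts, which therefore do not test it, and it remains open. These peaks touch none of the shared peaks.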

How the results depend on the processing

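The alternatives on autosomes, on peaks beside input regions, on equal list lengths, on the short shift, on merged sites and on chromosome names as deposited were chosen after seeing the data. The excess of HNF4A and FOXA2 overlap over chance, 32.3-fold, kept its direction and permutation p = 0.001 under all 9 alternatives, with folds of 19.5 to 75.6. The fold was 54.0 with an overlap of at least 50% of the shorter peak and 65.3 for centres within 200 bp. It was 49.6 with both lists cut at median score, 75.6 for placement on the whole chromosome and 19.5 for shifts of 2 to 10 kb. Chance overlap differs between these by construction. The shared part of the FOXA2 list, 30.7%, moved to 28.7% for centres within 200 bp and 26.8% with both lists cut at median score. It moved to 32.3% without peaks within 10 kb of input and 26.7% with HNF4A limited to its 9338 highest peaks. The shared part of the HNF4A list, 24.4%, moved to 22.9%, 21.6% and 26.6% under the first, second and last of these. Cutting both lists at median score also takes out lower-scoring partners. Those shares therefore do not go against the rise of sharing with score. The other 11 values of the shared parts stayed within the main intervals. Both changes of placement leave these shares unchanged by construction. Removing peaks that overlap input took out 0 FOXA2 and 2 HNF4A peaks, so under it the shares and the fold could hardly move. The higher scores of shared peaks kept direction and call under all 3 alternatives per list. Log2 differences were 0.30 to 0.35 for HNF4A and 0.44 to 0.51 for FOXA2. The removal of peaks that overlap input is among these alternatives and could hardly change the scores. Clusters of 5 or more peaks numbered 436, 399 without peaks within 10 kb of input and 222 when overlapping peaks were merged into sites, because a shared site then counts once. The number of ChIP peaks overlapping input, 2, was 0 with chromosome names as deposited, because the mitochondrial names differ. The alternatives on transcription start sites, motifs and gene lists were not run, for want of an mm9 sequence and annotation here. No paired analysis was possible because each group holds 1 library, and no library could be left out. The depth of the libraries is unknown, so single-factor peaks near a threshold cannot be separated from sites missed at low depth.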

Other observations

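The tests in this part were chosen after the main results were seen. Some clusters were made of peaks that coincided almost throughout: on chromosome 15 at 3178961 to 3201305 (mm9), all 5 HNF4A peaks, with scores of 38 to 57, were shared with 5 of 6 FOXA2 peaks, with scores of 13 to 60. Others leaned to HNF4A. Chromosome 7 at 20261979 to 20286633 held 11 HNF4A peaks with scores up to 142 and 2 FOXA2 peaks, both shared. Chromosome 3 at 10282831 to 10319304 held 8 HNF4A and 4 FOXA2 peaks, with 1 shared pair.

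Other clusters were made mostly or wholly of FOXA2 peaks, and the number of input regions within them varied. The largest, on chromosome 1 at 90108083 to 90206884, held 40 FOXA2 peaks with scores of 11 to 23, 6 HNF4A peaks with scores of 16 to 112, 2 of them shared, and 14 input regions. Chromosome 5 at 94311441 to 94406391 held 23 FOXA2 peaks, 0 HNF4A peaks and 22 input regions. Chromosome 5 at 93885959 to 93968243 held 22 FOXA2 peaks, 0 HNF4A peaks and 22 input regions. Input regions were fewer in 4 further clusters without an HNF4A peak: 3 beside 18 FOXA2 peaks on chromosome 4 at 145299830 to 145342330, and 4, 8 and 2 beside 15 FOXA2 peaks each on chromosome 4 at 41723375 to 41751045 and chromosome 5 at 94066898 to 94138497 and 95173651 to 95219215. The cluster on chromosome 13 at 12903970 to 12967342 held 11 FOXA2 peaks with scores of 11 to 12, no HNF4A peak and no input region.

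The hypothesis that both factors share neighbourhoods beyond the peaks they share was tested on the FOXA2 peaks without an overlap. Of these 6467 peaks 19.4% had their nearest HNF4A centre 1 to 10 kb away, against a median of 13.4% and at most 14.6% when the same peaks were moved by 10 to 100 kb. Over the whole FOXA2 list the same 1254 peaks were fewer than the median of 1392 placed peaks, because shared peaks have a nearer HNF4A centre in the data and lose it when moved. A count that a nearer centre cannot hide, of all HNF4A centres 1 to 10 kb away, gave 34.6 per 100 FOXA2 peaks against a median of 20.3 and at most 21.8 after shifts. For peaks without an overlap it gave 27.1 against a median of 17.9, and for shared peaks 51.6 against 25.5. A shared FOXA2 peak lies on an HNF4A peak, so its count also reflects the spacing of HNF4A peaks among themselves. The count over the whole list includes these peaks, so only the count for peaks without an overlap bears on the hypothesis. The excess for peaks without an overlap goes with common neighbourhoods. Whether it reflects joint regulation or only the spacing of open chromatin was not tested.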
